A study of Mus musculus with 8 samples.

How the data were processed

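Small RNA libraries were made with a QIAseq miRNA kit and sequenced single-end on a NextSeq instrument from the input RNA and the anti-HA AGO2 IP of B cells from spleens of mice whose AGO2 carries the HA epitope, per the labels. Reads were aligned with STAR 2.7.9a to mm10, and SAMtools 1.15 was used, per the submitters' processing notes. The deposited tables hold raw counts per miRNA gene, and their headers name deduplicated alignments, per the file headers. The method of deduplication, the counter, its strand setting and its treatment of reads that map to several places are not given in the sources used here. The highest count, 257070 for Mir93, falls in a feature of 88 nt, more than distinct start positions allow, so duplicates were not removed by mapping position alone. There are 2 tables, of resting and of proliferating cells, with the same 2202 features, so that cell state and table coincide. Features are 39 to 442 nt long (median 89) and each covers both arms of its hairpin. Reads shared by near-identical copies (among them let-7a, let-7c, miR-16, miR-19b, miR-24, miR-26a, miR-92a and miR-181) or by features overlapping on opposite strands cannot be assigned with certainty. Values of single copies are uncertain for that reason.

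Features were named by exact match of chromosome, start and end to RefSeq genes of the same assembly. This named 1179 features and left 1023 unnamed, 6 of which matched several genes. Of the 560 features with a count, 46 were unnamed, and unnamed features held 1.06% of all counts. RefSeq symbols are used, such as Mir146 for the miR-146a gene, Mir92-1 for miR-92a-1 and Mir18 for miR-18a. Host genes and overlapping snoRNA, scaRNA or tRNA genes were taken from the same RefSeq table by overlap of gene spans, which does not separate exons from introns. Groups came from titles and cell type labels, and replicate numbers from titles. Counts of the 2 libraries of each group differed by more than sampling noise (chi-square per degree of freedom 9.70 or more), so none was treated as a duplicate.

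CPM were computed from the deposited counts with TMM factors, which ranged from 0.797 to 1.34. Shares in percent are of all counts of a library, without TMM, with exact (Clopper-Pearson) 95% intervals for single libraries. The tables hold 1 RNA class, so shares between RNA classes were not computed, and none of the 15 fixed repeat and RNA class lists had a member. Library totals from 213418 to 1681148 put the floor of 3 counts between 1.78 and 14.1 CPM of a single library's total, without TMM factors, while the floors behind fold bounds use TMM. Features were kept by edgeR's filterByExpr with a minimum count of 10, which left 219 features, 6 of them unnamed. edgeR 4.0.16 in R 4.3.3 fitted a quasi-likelihood model with the 4 groups to all 8 libraries (4 residual degrees of freedom), and 5 contrasts were tested 2-sided with Benjamini-Hochberg adjustment within each: IP against input in each state, their difference, and resting against proliferating cells in input and in IP. Log2 fold changes are edgeR's, and SE is the absolute log2 fold change divided by the square root of the quasi-likelihood F statistic. Where a group had no count, the fold is a bound against 3 counts over the group, and with 1 to 3 counts a ratio with its exact counting interval is given, which covers counting error only.

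Before the data were examined, lists of miRNAs and the rule for named features were fixed. For each contrast the rule takes the 10 largest rises and the 10 largest falls among features past the threshold with a mean CPM of at least 10 and with the libraries of the groups apart, then the 10 most abundant features per group, up to 4 most abundant members of each list as examples, and Mir150, Mir155, Mir21a, Mir451a, Mir486 and let-7 features in any case. Limma 3.58.1's camera (voom weights, preset correlation 0.01) tested the 8 lists with at least 3 tested members: let-7, the miR-17 cluster and its paralogs, resting lymphocyte, lymphocyte activation, haematopoietic, mirtron, miR-34 and epithelial miRNAs. None of the 12 list calls at an adjusted p under 0.05 held with an estimated correlation. That setting rests on the 4 residual degrees of freedom, so a loss under it need not come from correlated members. Smaller lists are given by their members or shares. The Dlk1-Dio3 list had no tested member, at 0.00303% ± 0.00193 of the resting input, and the Sfmbt2 list had 2, Mir669c and Mir467c. The list of AGO2-processed miRNAs, Mir486 and Mir3107, was at 0.00116% ± 0.00165 of the resting input, but these features overlap on opposite strands, so their counts say little about their level. The neural list was at 0.000109% ± 0.000154 of the proliferating IP, the erythroid list at 0.0186% ± 0.0102 of the resting input and the stromal list at 0.00886% ± 0.00320 of the resting IP. Mir144 gave 41 of 41 and 91 of 100 counts of the erythroid list in the resting inputs. Mir451a could not be assigned and Mir486 and Mir3107 overlap, so this share does not give the level of erythroid miRNAs. The striated muscle list had 0 counts, where 3 counts would be 14.1 CPM of the total, without TMM factors, in the shallowest library. Simulated counts gave each feature the same mean in all groups, then changed a single group by equally many rises and falls. The data hold more changes between states, so recovery there may differ from the rates given next. On simulated counts for the 219 features with 60 changed, the resting IP contrast recovered 28.5% of 2-fold and 69.5% of 4-fold changes, the proliferating IP contrast 26.3% and 69.3%, the interaction 9.33% and 39.5%, the input contrast 22.5% and 64.8%, and the contrast within the IP 31.0% and 71.8%. Alternatives were DESeq2 1.42.0 (size factors and Wald test), library totals, upper-quartile factors, other filters on low counts, a replicate block, fits of only the 4 libraries compared, an added fold threshold, each library left out, and for lists an estimated correlation and fry. Permutation tests and intervals used scipy 1.17.1 and Python 3.11.15.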

Results

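Small RNA was sequenced from mouse spleen B cells and from the RNA bound to AGO2 in the same kind of cells. AGO2 is an Argonaute protein that carries microRNAs (miRNAs) to their targets, and in these animals both copies of its gene encode an HA epitope, so that an anti-HA antibody precipitates it. B cells were isolated by depleting CD43-bearing cells and were taken either resting or after activation in culture (proliferating). The 8 libraries fall into 4 groups of 2: resting input, resting immunoprecipitate (IP), proliferating input and proliferating IP. According to the labels, cells without the epitope gave no RNA in the IP and no library, so the input is the reference for each IP. The deposited tables hold counts for 2202 Ensembl miRNA genes, each gene counted once for both arms of its hairpin. Library totals were 358764 and 386598 counts in the resting inputs, 1681148 and 788869 in the resting IPs, 276287 and 213418 in the proliferating inputs, and 795229 and 1376045 in the proliferating IPs. The log2 CPM of the 2 libraries of a group correlated across features with r from 0.960 to 0.981, and 219 features had enough counts to be tested. The labels do not state whether the 2 libraries of a group came from separate animals, so p-values measure the spread between these samples, which may be technical. Most of that spread estimate was shared over features, with 36.6 prior against 4 residual degrees of freedom. Very small p-values therefore rest only in small part on a feature's own libraries.

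Ranks, shares and list results here and below cover only features with counts. Mir142, Mir191, Mir24-1, Mir24-2 and Mir378a of the haematopoietic list had no count. The same holds for Mirlet7e and Mirlet7f-1 of the let-7 list. Each overlaps a feature on the opposite strand, so its level is unknown and it could rank among the most abundant. Features of near-identical copies had few counts too. In resting input replicate 1, Mir19b-1 had 1 and Mir19b-2 had 7 counts, against 421 for Mir19a. Mirlet7a-1 had 7 there, and Mir26a-2 had 62 against 9431 for Mir26b. Shares, ranks and list results may therefore leave out much of miR-19b, let-7a and miR-26a. Among counted features of the resting input the most abundant miRNA gene was Mir150 (chromosome 7, 45121757 to 45121821, mm10), a lymphocyte miRNA known to restrain Myb, at 30.5% ± 0.352 of the counts (mean ± SD, n = 2 here and below). Mir146, the gene of miR-146a, followed at 7.80% ± 0.0682, then Mir29a at 7.41% ± 0.765, Mir342 at 5.89% ± 0.606 and Mir93 at 5.54% ± 0.264. The resting IP held 16.6% ± 3.52 Mir150, 12.6% ± 2.31 Mir146, 8.22% ± 0.768 Mir26b and 8.19% ± 1.48 Mir93. In the proliferating input Mir155, which is made from the activation-induced Mir155hg transcript, led with 15.1% ± 0.370, followed by Mir146 at 13.5% ± 0.476 and Mir93 at 12.3% ± 0.129. The proliferating IP was led by Mir93, which lies within the Mcm7 gene (chromosome 5, 138165523 to 138165610), at 20% ± 1.90, then Mir155 at 11.6% ± 1.2, Mir146 at 10.7% ± 0.368, Mir21a at 10.7% ± 2.77 and Mir25 at 9.98% ± 2.53. The unnamed feature ENSMUSG00000105167.1 (chromosome 15, 80082847 to 80082954, within Rpl3) overlaps the snoRNA gene Snord43 and took 4.58% ± 0.894 of the resting and 3.37% ± 0.0699 of the proliferating input. The 10 most abundant features took from 74.5% to 83.3% of a library. Mir451a could not be assigned to a single feature, and Mir486, which overlaps Mir3107 on the opposite strand so that its reads are not assigned with certainty, had 10 counts in all libraries together. Neither was tested.

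The comparison of resting with proliferating cells in the input shows which miRNAs differ between the cell states before AGO2 is selected. Of 219 features, 108 differed, 51 higher and 57 lower in resting cells (edgeR quasi-likelihood test, Benjamini-Hochberg adjusted p under 0.05). Mir150 was 11.6 times as high in resting cells, at 297833 ± 15266 CPM against 25613 ± 4496 CPM (log2 fold change 3.54, SE 0.25, edgeR adjusted p = 4.9e-15). Mir155 (chromosome 16, 84714140 to 84714204) went the other way, at 11190 ± 1366 CPM against 115335 ± 6160 CPM (log2 fold change -3.37, SE 0.24, edgeR adjusted p = 4.9e-15). Of the 11 tested members of the resting lymphocyte list (miR-150 and the miR-26, miR-29 and miR-30 families), 8 rose, 0 fell and 3 did not pass, and 8 rose when adjusted over the list alone. Among them Mir29a rose by 2.22, Mir30d by 1.64 and Mir26b by 0.54 on the log2 scale. The list's median was 1.39 (camera adjusted p = 1.5e-04 with a preset correlation, adjusted p = 0.23 with an estimated correlation). Of the 9 members of the lymphocyte activation list, 6 fell and 3 did not pass, with 6 lower when adjusted over the list alone. Mir155 and Mir21a (-0.58) were among those that fell, while Mir146 (-0.44, edgeR adjusted p = 0.091) and Mir221 (-0.66, edgeR adjusted p = 0.076) did not pass. The median of that list was -1.73 (camera adjusted p = 0.0043, adjusted p = 0.23 with an estimated correlation).

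The miR-17 cluster and its paralogs, miRNAs known to promote lymphocyte growth, were lower in the resting input for 11 of 15 members (11 adjusted over the list alone). Mir20a fell by 1.40, Mir92-1 by 0.94 and Mir93 by 0.80 on the log2 scale, while Mir25 (-0.44) did not pass. The median of the list was -1.26 (camera adjusted p = 3.4e-04, adjusted p = 0.23 with an estimated correlation). Of the miR-34 list, Mir34a (chromosome 4, 150068454 to 150068555), a p53 target, was lower by 3.17 and Mir192 rose by 1.37 on the log2 scale. Of the 10 tested let-7 features 1 rose, Mirlet7c-2 (1.98), and 3 fell, among them Mirlet7i (-0.60) and Mirlet7a-2 (-2.07), and the list did not pass (camera adjusted p = 0.54). In the haematopoietic list 4 of 14 rose and none fell (2 rose adjusted over the list alone, camera adjusted p = 0.10), with Mir342 at 0.54. The mirtron list had 1 of 5 lower, Mir877 (-1.78), 0 adjusted over the list alone, and its camera adjusted p was 0.54. Several of the largest differences rest on few counts. Mir542 was at least 18.7-fold higher, Mir326 at least 17.0-fold and Mir378d at least 3.90-fold higher in resting input, against a floor of 3 counts over the proliferating inputs, where none was counted. Mir6399 was at least 10.4-fold, Mir7683 at least 5.58-fold, Mir8112 at least 4.38-fold and Mir7661 at least 3.99-fold lower in resting input, against the same floor over the resting inputs. With 1 count in the proliferating inputs, Mir6516 had a ratio of 31.8 (95% exact counting interval 5.37 to 1288) and Mir181a-2 of 24.3 (95% exact counting interval 4.02 to 991). Mir455 and Mir3971, with 4 counts each in the proliferating inputs, were higher in resting cells by 4.77 and 4.42 on the log2 scale. Mir183 fell by 3.59, and Mir96, with 6 counts in the resting inputs, by 3.54.

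miRNAs of other cell types also moved with cell state in the input, beside the lists above. Mir223 (chromosome X, 96242817 to 96242926), typical of myeloid cells, rose by 3.18 on the log2 scale in resting cells (SE 0.33, edgeR adjusted p = 1.9e-10), and Mir144, typical of erythroid cells, rose by 3.42. In single libraries the Mir223 share was 1.153% (95% exact interval 1.12 to 1.19) and 2.86% (2.80 to 2.91) in the resting inputs, against 0.221% (0.204 to 0.239) and 0.339% (0.315 to 0.364) in the proliferating inputs. These intervals cover counting error only. Of the epithelial miR-200 family, Mir141 (1.54) and Mir200a (2.89) rose and 3 of 5 did not pass (camera adjusted p = 0.21). The endothelial Mir126a (-1.41) and the hepatocyte Mir122 (-2.54) were lower in resting cells. Mir126a lies opposite Mir126b, so its reads are not assigned with certainty, here and in the contrasts below. Mir122 had only 3 and 4 counts in the resting inputs. Scaling set the balance of directions: of the calls in the input, 37 were higher and 75 lower with library totals, and 59 higher and 39 lower with upper-quartile factors.

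**Figure D1:**
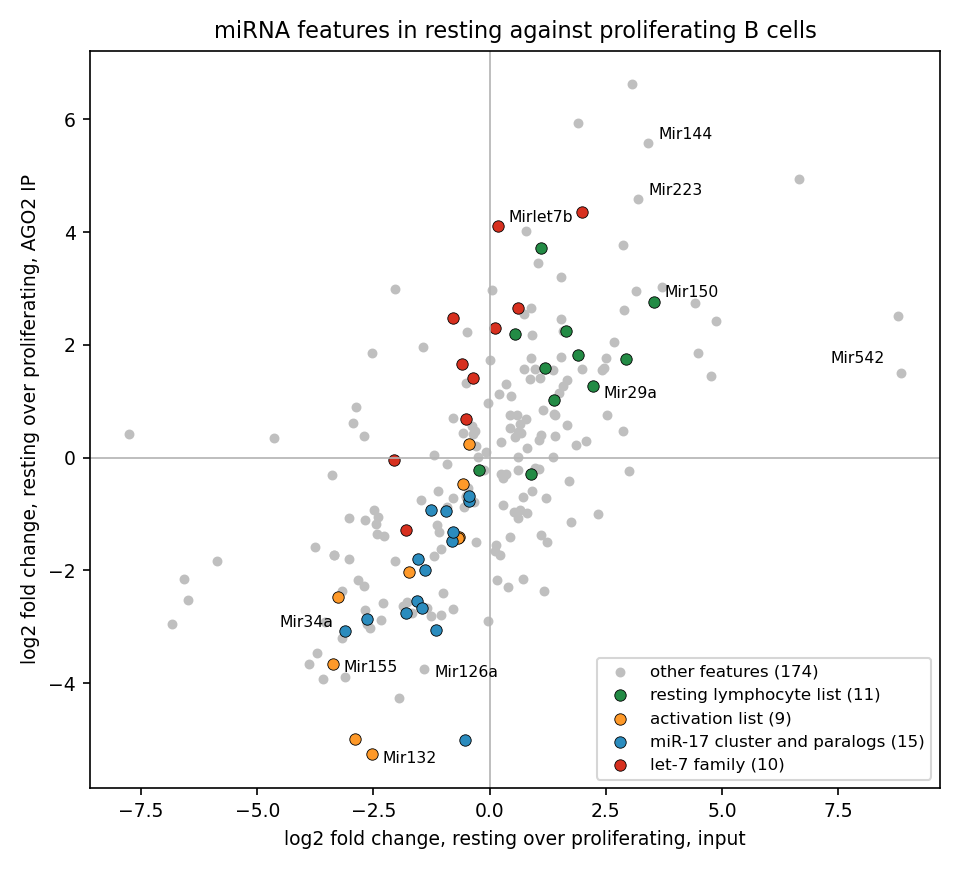
Each point is 1 of 219 tested miRNA features. The x axis gives the log2 fold change of resting over proliferating cells in the input and the y axis the same in the AGO2 IP, with the fixed lists in colour. Mir150 lies high on both axes (3.54 and 2.77), Mir155 low on both (-3.37 and -3.65), and let-7 features lie higher on the y axis than on the x axis.

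The same comparison within the IP shows which miRNAs differ among those precipitated with AGO2. Of 219 features, 114 differed, 52 higher and 62 lower in resting cells (edgeR, adjusted p under 0.05). The Mir150 level was 6.81 times as high in the resting IP (log2 fold change 2.77, SE 0.25, edgeR adjusted p = 2.4e-12). Mir155 was lower by 3.65 (SE 0.24, edgeR adjusted p = 5.4e-16). let-7 features were higher in the resting IP for 7 of 10 members (8 adjusted over the list alone), with 1 lower, Mir98 (-1.28). Mirlet7b (chromosome 15, 85707319 to 85707403) rose by 4.11 (SE 0.32, edgeR adjusted p = 3.7e-14), Mirlet7i by 1.67 and Mirlet7g by 1.41. Their median was 1.98 (camera adjusted p = 0.0033, adjusted p = 0.31 with an estimated correlation). The resting lymphocyte list again had 8 of 11 higher (8 adjusted over the list alone), with Mir26b at 2.19, Mir30d at 2.26 and Mir29a at 1.27 (camera adjusted p = 2.5e-04, adjusted p = 0.21 with an estimated correlation). The miR-17 cluster and its paralogs were lower for 14 of 15 members (14 adjusted over the list alone), with Mir20a at -1.99, Mir93 at -1.32 and Mir25 at -0.77 (camera adjusted p = 5.9e-06, adjusted p = 0.13 with an estimated correlation). The activation list had 6 of 9 lower (6 adjusted over the list alone), among them Mir132 (-5.26), and Mir221 was at -1.41 (camera adjusted p = 0.011, adjusted p = 0.13 with an estimated correlation). Mir212, with 2 counts in the resting IPs, had a ratio of 39.8 (95% exact counting interval 10.6 to 335) in favour of proliferating cells.

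All 5 miR-200 family features rose in the resting IP, from 1.74 for Mir200c to 4.03 for Mir200b on the log2 scale, each also past 0.05 adjusted over the list alone (camera adjusted p = 0.0033, adjusted p = 0.13 with an estimated correlation). Mir223 rose by 4.59, Mir144 by 5.58 and Mir10b, typical of stromal cells, by 1.77, while Mir126a fell by 3.74. Other large rises were Mir139 (3.78), Mir26a-2 (3.73) and Mirlet7c-2 (4.35). The rise of Mir6236 (3.46) rests on resting IP replicate 2 (0.507% of its counts against 0.0362% in replicate 1) and was 0.69 without it (edgeR adjusted p = 0.15). Mir99a, with 2 counts in the proliferating IPs, had a ratio of 86.6 (95% exact counting interval 23.6 to 720) and Mir378d, also with 2, of 38.4 (95% exact counting interval 10.3 to 322). Mir1983 (-4.27), Mir183 (-3.92), Mir182 (-3.90), Mir34a (-3.20), Mir1934 (-3.65) and Mir6960 (-3.46) fell. The haematopoietic list had 1 of 14 higher and 5 lower, with Mir23a at -1.65 (camera adjusted p = 0.95). The miR-34 list, with Mir192 higher (1.55) and Mir34a lower, did not pass (camera adjusted p = 0.95) and neither did the mirtron list (camera adjusted p = 0.77). Of the features called in input and IP, 33 were higher in resting cells in both, where independent lists would share 12.1, and 41 were lower in both, against 16.1. The directions were opposed for 2 features: ENSMUSG00000105167.1 was higher in resting input and lower in resting IP, and Mirlet7i the reverse. With upper-quartile factors the split of calls in the IP was 75 higher and 38 lower.

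The comparison of IP with input in resting cells shows which miRNAs are over- or under-represented with AGO2. Of 219 features, 63 differed, 29 higher and 34 lower in the IP (edgeR, adjusted p under 0.05). Mir26b (chromosome 1, 74394310 to 74394394, within Ctdsp1) rose 3.51-fold, from 27220 ± 1139 to 95513 ± 20428 CPM (log2 fold change 1.81, SE 0.23, edgeR adjusted p = 8.3e-08). Mirlet7b rose 3.67-fold, from 2817 ± 172 to 10349 ± 3798 CPM (log2 fold change 1.88, SE 0.29, edgeR adjusted p = 1.8e-06). The let-7 list had 4 of 10 features higher in the IP (5 adjusted over the list alone) and none lower. Mirlet7f-2 rose by 1.69, Mirlet7d by 1.07 and Mirlet7g by 0.91, and Mirlet7i was at 0.61 (edgeR adjusted p = 0.059). Their median was 0.76 (camera adjusted p = 0.012, adjusted p = 0.58 with an estimated correlation). The miR-17 list had 6 of 15 higher and 1 lower, with Mir92-1 at 1.61, Mir25 at 0.98 and Mir93 at 0.79 (camera adjusted p = 0.056). The resting lymphocyte list went both ways, 3 higher and 5 lower of 11 (camera adjusted p = 0.64): Mir29a fell by 1.44 and Mir150 by 0.66 (SE 0.23, edgeR adjusted p = 0.026). In the activation list 2 of 9 rose, Mir21a (1.30) and Mir146 (0.95), 2 fell, and Mir155 was at -0.06 (SE 0.22, edgeR adjusted p = 0.87). The haematopoietic list had 1 of 14 higher, Mir15b (1.10), and 2 lower. No member of the miR-34 or mirtron lists passed.

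The largest rises in the resting IP included Mir200b (2.68), Mir429 (2.30) and Mir200c (2.08) of the epithelial list, whose camera adjusted p was 0.13 and in which Mir200a (-1.33) was lower when adjusted over the list alone, and Mir190b (2.17), Mir32 (2.06), Mir26a-2 (1.84) and the stromal Mir10b (2.38). The myeloid Mir223 (0.35, edgeR adjusted p = 0.40) and the erythroid Mir144 (-0.03) did not pass. Mir669c of the Sfmbt2 cluster, with 1 count in the resting inputs, had a ratio of 24.5 (95% exact counting interval 4.26 to 984). The largest falls were Mir677, within Atp5b, at -5.24 (SE 0.85, edgeR adjusted p = 4.7e-06), and Gm24148, within the nucleolin gene Ncl, at -5.03 (SE 0.39, edgeR adjusted p = 4.9e-14). ENSMUSG00000105167.1, which overlaps Snord43, fell from 44605 ± 6955 to 1879 ± 176 CPM (log2 fold change -4.57, SE 0.28, edgeR adjusted p = 2.7e-17). Mir5121 (chromosome 7, 45126918 to 45126991), which overlaps Snord33 within Rpl13a, fell by 4.51. Mir331 (-3.72), Mir1949 (-3.80), Mir6516 (-3.64), Mir181b-1 (-3.59), Mir1249 (-3.54) and Mir30c-1 (-3.03) fell as well. With library totals the calls were 25 higher and 41 lower, and with upper-quartile factors 33 higher and 23 lower.

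In proliferating cells 59 features differed between IP and input, 29 higher and 30 lower in the IP (edgeR, adjusted p under 0.05). The miR-17 cluster and its paralogs were higher in the IP for 11 of 15 members (11 adjusted over the list alone) and lower for none. Mir93 rose from 94018 ± 3699 to 233382 ± 21597 CPM (log2 fold change 1.31, SE 0.21, edgeR adjusted p = 5.1e-06), Mir92-1 by 1.60, Mir19a by 1.52, Mir20a by 1.40 and Mir25 by 1.31. The list's share of all counts was 23.8% ± 0.190 in the input and 40.1% ± 1.76 in the IP. In resting cells the list's share also rose, from 11.1% ± 0.0558 of the input to 18.5% ± 1.26 of the IP. The list's median log2 fold change in proliferating cells was 1.31 (camera adjusted p = 5.8e-07, adjusted p = 0.24 with an estimated correlation). let-7 features were lower in the IP for 4 of 10 members (5 adjusted over the list alone) and higher for none. Mirlet7i (chromosome 10, 122985640 to 122985724) fell from 47862 ± 5593 to 15099 ± 5718 CPM (log2 fold change -1.66, SE 0.25, edgeR adjusted p = 1.9e-06), and Mirlet7b by 2.05, Mirlet7a-1 by 2.30 and Mirlet7g by 0.85 on the log2 scale. The let-7 share was 8.64% ± 0.696 of the input and 2.36% ± 0.719 of the IP, with a median log2 fold change of -1.62 (camera adjusted p = 0.010, adjusted p = 0.84 with an estimated correlation). Mir21a (1.18) and Mir221 (1.41) of the activation list rose and 2 of its 9 members fell, while Mir155 was at 0.23 (SE 0.22, edgeR adjusted p = 0.48) and Mir146 at 0.27 (camera adjusted p of the list = 0.93). Of the haematopoietic list 4 of 14 rose, including Mir23a (1.82), Mir15b (1.74) and Mir342 (0.72) (camera adjusted p = 0.17). The resting lymphocyte list had 1 of 11 higher and 3 lower, among them Mir30d (-1.08), and Mir150 was at 0.11 (camera adjusted p of the list = 0.29). No member of the epithelial, miR-34 or mirtron lists passed.

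Of the markers of other cell types, the endothelial Mir126a, which lies opposite Mir126b, rose in the proliferating IP by 1.48. Mir223 and Mir122 fell by 1.06 and 2.43. Other rises were Mir455 (2.57), Mir1983 (2.10), which overlaps an isoleucine tRNA gene, Mir19b-2 (1.80), Mir23b (1.61) and Mir339 (1.56). Mir190a, with 3 counts in the proliferating inputs, had a ratio of 12 (95% exact counting interval 4.0 to 59.2). Among the falls, Mir5099 was lower by 4.66 (SE 0.42, edgeR adjusted p = 1.1e-11), Mir677 by 3.84, Mir6240 by 3.80, Mir1949 by 3.59 and Mir146b by 3.35. Mir6399, with 2 counts in the IPs, was higher in the input by a ratio of 37.9 (95% exact counting interval 9.48 to 329), and Mir1291, with 2, by 23.3 (95% exact counting interval 5.48 to 209). Mir142b (-3.82) and ENSMUSG00000092915.1 also fell, the latter, with 3 counts in the IPs, by a ratio of 24.3 (95% exact counting interval 7.41 to 126), but they lie opposite Mir142 and Mir191, and the source of such reads cannot be assigned because the strand setting of the counting is not stated. The count of calls depended on single libraries: it was 33 without proliferating input replicate 1, 30 without proliferating input replicate 2 and 37 without proliferating IP replicate 2. With library totals 16 were higher and 60 lower.

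**Figure D2:**
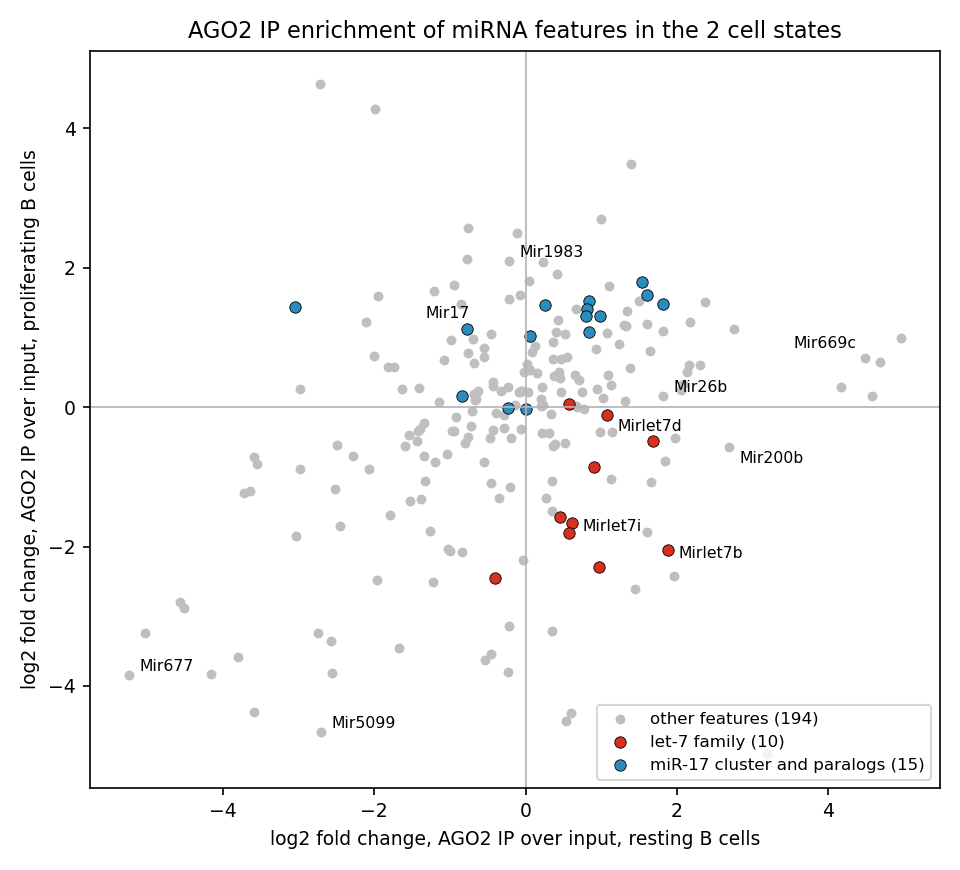
Each point is 1 of 219 tested miRNA features. The x axis gives the log2 fold change of AGO2 IP over input in resting cells and the y axis the same in proliferating cells. Most let-7 features (red) lie right of and below 0, Mirlet7b at 1.88 and -2.05, and most features of the miR-17 cluster and its paralogs (blue) lie above 0 on the y axis.

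The interaction term asks whether IP enrichment differed between the cell states, and its values are the log2 enrichment in resting cells minus that in proliferating cells. It was past the threshold for 38 of 219 features, 17 higher and 21 lower in resting cells (edgeR, adjusted p under 0.05). let-7 had 6 of 10 features with higher enrichment in resting cells (7 adjusted over the list alone). Mirlet7b differed by 3.92 (SE 0.41, edgeR adjusted p = 1.3e-09), Mirlet7i by 2.27 (SE 0.35, edgeR adjusted p = 1.2e-05), Mirlet7f-2 by 2.18, Mirlet7g by 1.76, Mirlet7d by 1.18 and Mirlet7a-1 by 3.27. The let-7 median was 2.12 (camera adjusted p = 5.2e-08, adjusted p = 0.30 with an estimated correlation). Mir26a-2 (2.61) and Mir26b (1.65) of the resting lymphocyte list and Mir200b (3.25) and Mir200c (1.74) of the epithelial list were also higher in resting cells, while 1 member of the resting lymphocyte list was lower, and the lists did not pass (camera adjusted p = 0.86 and 0.058). The miR-17 list had 2 of 15 lower, including Mir17 (-1.90), with a camera adjusted p of 0.058. Mir132 (-2.74) was the member of the activation list that differed (camera adjusted p = 0.86), and Mir155 (-0.29), Mir150 (-0.77) and Mir21a (0.12) did not pass. Of the haematopoietic list 3 of 14 were lower, with Mir23a at -1.77 (camera adjusted p = 0.068). Mir3964 (-3.24), Mir455 (-3.33), Mir125a (-2.40) and Mir1983 (-2.32) were lower in resting cells. Of the markers of other cell types, Mir223 (1.40) and Mir122 (4.40) were higher and Mir126a (-2.34) lower. Over left-out libraries Mir223 ranged from 0.69 to 2.32, Mir122 from 3.96 to 5.13 and Mir126a from -3.20 to -1.82.

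The features called in both states were partly shared. Of 29 features higher in the IP in each state, 13 were the same, where independent lists would share 3.84, among them Mir21a, Mir25, Mir93, Mir92-1, Mir15b and Mir190b. Of 34 and 30 lower features, 11 were the same, against 4.66, among them Mir677, Gm24148, ENSMUSG00000105167.1, Mir5121 and Mir5099. Mirlet7g and Mirlet7b were higher in the resting IP and lower in the proliferating IP, and Mir17 was the reverse. The log2 fold changes in the 2 states correlated across features with r = 0.322, and features are not independent replicates. The number of interaction calls was sensitive to processing: it was 25 with DESeq2 size factors, 22 with upper-quartile factors (15 higher, 7 lower), 19 with a filter of at least 10 CPM, 11 without proliferating input replicate 1 (11 higher, 0 lower), 13 without proliferating input replicate 2 (13 higher, 0 lower) and 25 without resting input replicate 1 (21 higher, 4 lower). No lower call held without either of the proliferating inputs. With library totals 20 were higher and 7 lower.

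**Figure D3:**
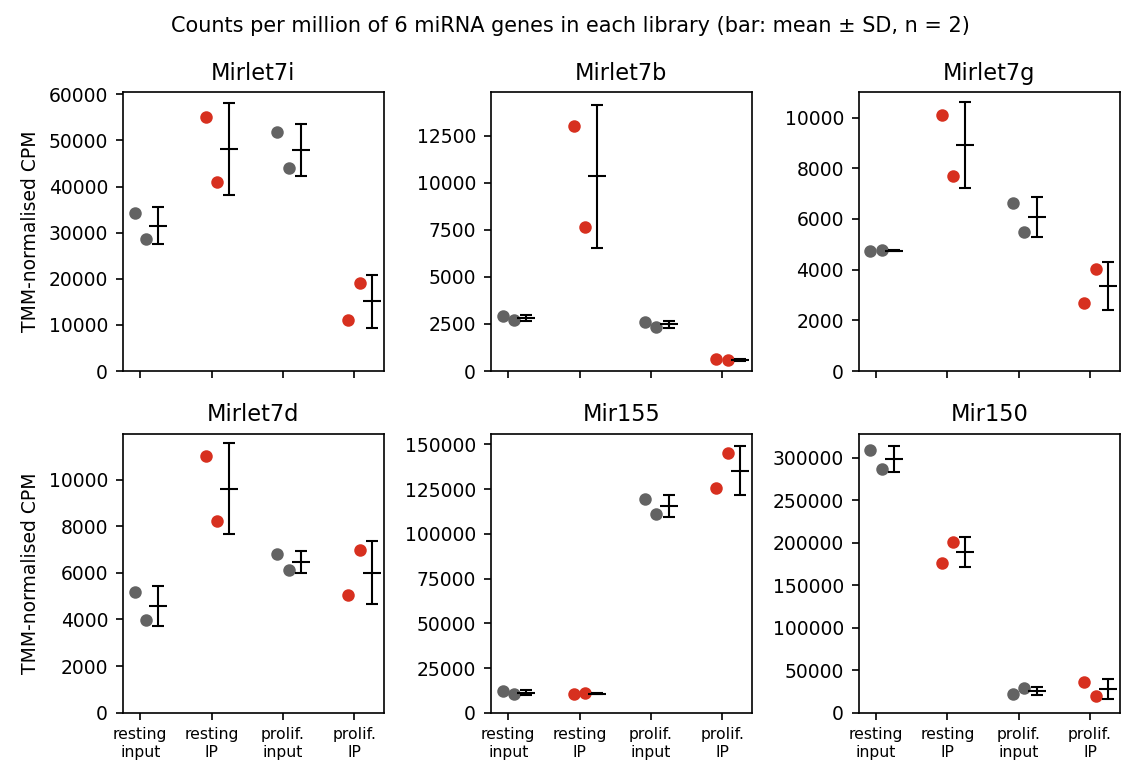
TMM-normalised CPM of 6 miRNA genes in each library, with inputs in grey, IPs in red and the mean ± SD of the 2 libraries as a bar. Mirlet7b lies at 2817 and 10349 CPM in resting input and IP, and at 2479 and 600 CPM in proliferating input and IP, while Mir150 and Mir155 differ mainly between cell states.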

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

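The tests of scaling, of single libraries and of other cell types for let-7, those of overlapping small RNA genes and those of opposite strands were chosen after the results were seen. The results here share 1 reason for a closer look: the effect of the IP differed between resting and proliferating cells by the interaction term. For let-7 the difference was 3.92 for Mirlet7b, 3.27 for Mirlet7a-1, 2.27 for Mirlet7i, 2.18 for Mirlet7f-2, 1.76 for Mirlet7g and 1.18 for Mirlet7d on the log2 scale, and the median of the list was 2.12. Features with higher enrichment in resting cells were also ENSMUSG00000076258.1 (5.03, but -1.97 without resting IP replicate 2, and lost in 5 of 8 leave-outs and 6 of 10 other settings), Mir122 (4.40), Mir200b (3.25), Mir26a-2 (2.61), Mir5099 (1.96), Mir7j (1.84), Mir200c (1.74), Mir26b (1.65) and Mir223 (1.40). Lower in resting cells were Mir23a (-1.77), Mir301b (-1.89), Mir17 (-1.90), Mir1983 (-2.32), Mir126a (-2.34), Mir125a (-2.40), Mir1249 (-2.73), Mir132 (-2.74), Mir3964 (-3.24), Mir455 (-3.33) and Mir542 (-7.35). The Mir542 value is a fitted one that depends on the prior count, since the proliferating inputs had no count. Of these 26 features, 8 stayed past the threshold without each of the 8 libraries in turn: Mirlet7b, Mirlet7i, Mirlet7f-2, Mirlet7g, Mir200b, Mir26a-2, Mir26b and Mir7j. Without proliferating input replicate 1, 16 of the 26 were lost, and without proliferating input replicate 2, 15. Under the other settings, 15 of the 26 stayed past the threshold in all. Mir1249 was lost under 7 of 10, Mir223 under 6 and Mirlet7a-1 under 4, and Mir542, Mir132 and Mir301b held under only 5 of 10.

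Of 10 let-7 features, 4 were past the threshold as lower in the proliferating IP and 4 as higher in the resting IP. The list results did not hold with an estimated correlation (adjusted p = 0.84 and 0.58, and 0.30 for the interaction). The let-7 median of the difference, not taken relative to other features, stayed at 2.19 to 2.44 under 3 other scalings. These scalings moved the interaction median of all features only from -0.17 to between -0.10 and 0.19. They were too alike to decide whether scaling is a cause, and a scaling outside these was not tested. A single library is argued against as the cause: leaving out each in turn gave a let-7 median relative to all features of 1.86 at the lowest. RNA of other cell types was not tested for the fall in proliferating cells. For the rise in resting cells it stays open: the let-7 median between the inputs was -0.43, but Mir223 was higher in resting cells despite the depletion of CD43-bearing cells, and the replicate with more Mir223 (2.94% against 1.45% of the resting IP) had less let-7 (6.91% against 7.89%). A difference in AGO2 loading between the cell states remains an untested biological candidate. Cell state coincides with the table in which the libraries were counted, though an effect shared by IP and input of a table cancels in the interaction.

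Features that overlap a snoRNA, scaRNA or tRNA gene were low in the IP as a set. Of the 10 such tested features, 2 passed as lower in resting cells and 5 in proliferating cells. They had a median log2 fold change of -1.75 in resting and -2.49 in proliferating cells, and their medians lay away from those of the 209 other features by -1.78 and -2.65 (2-sided permutation p = 0.0019 and 0.00023). The set was chosen after the results were seen and holds ENSMUSG00000105167.1 and Mir5121, which were among the largest falls. These p-values are therefore no independent test. The difference nearer to 0, -1.78, is consistent with reads of another RNA class that was not bound to AGO2. Mir1983, over a tRNA gene, passed the other way in proliferating cells (2.10), and Mir1843a was at 0.31 without passing. Without these features the counts of calls were 62 and 55 for the IP contrasts. No biological explanation was tested.

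Some miRNA genes known to be abundant in blood cells had no count, among them Mir142 (chromosome 11, 87756864 to 87756927), Mir191, Mir24-1, Mirlet7e and Mirlet7f-1. Each lies inside a feature annotated on the opposite strand. Of 34 features in that position 0 had a count, against 509 of 1130 other named features (45%, Fisher exact p = 2.6e-09). This is consistent with a counter that ignored strand and dropped reads falling in both features. Whether any of these miRNAs is truly low cannot be told apart from that, since 0 of these features was measured free of the overlap.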

How the results depend on the processing

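The crossed replicate block and the fits without features over another small RNA gene were chosen after seeing the data, and the causes of the changes below were not tested. Interaction calls, 38 in the design as planned, were 25 with DESeq2 size factors in edgeR, 22 with upper-quartile factors and 19 with a filter of at least 10 CPM in at least 2 libraries, and over left-out libraries ranged from 11 (without proliferating input replicate 1) to 46 (without resting IP replicate 2). Calls in the proliferating IP, 59 as planned, ranged over left-out libraries from 30 (without proliferating input replicate 2) to 63, and were 76 with library totals. The total calls of the other contrasts stayed within 1.5 times under all alternatives run, but their splits moved: over left-out libraries the lower calls ranged from 17 to 44 in the resting IP (34 as planned) and from 34 to 52 in the input (57 as planned), and the higher calls from 32 to 62 in the input (51 as planned). The interaction had no lower call without either proliferating input. A left-out library leaves a lone sample that is assumed to vary like the other groups. Scaling moved the median log2 fold change of all features: with library totals to -0.50 in the proliferating IP contrast and -0.40 in the input contrast, against 0.11 and -0.04, and with upper-quartile factors to 0.45 in the contrast within the IP, against -0.21. It moved the split into higher and lower calls from 29 and 34 to 25 and 41 (totals) or 33 and 23 (upper quartile) for the resting IP, from 29 and 30 to 16 and 60 (totals) for the proliferating IP, from 17 and 21 to 20 and 7 or 15 and 7 for the interaction, from 51 and 57 to 37 and 75 or 59 and 39 for the input, and from 52 and 62 to 75 and 38 (upper quartile) within the IP. The let-7 median of the interaction was 1.49 to 2.82 over all settings, and the miR-17 median in the proliferating IP 0.70 to 1.42, neither taken relative to other features. Camera with an estimated correlation has only the 4 residual degrees of freedom, so a loss under it need not come from correlated members. Between IPs the epithelial and activation lists were lost despite negative estimated correlations (-0.12 and -0.043). All 12 list calls were lost with an estimated correlation. The adjusted p of let-7 was then 0.58 in the resting IP, 0.84 in the proliferating IP, 0.30 for the interaction and 0.31 between IPs, that of the miR-17 list 0.24, 0.23 and 0.13 (proliferating IP, between inputs, between IPs), that of the resting lymphocyte list 0.23 and 0.21 and of the activation list 0.23 and 0.13 (inputs, IPs), and that of the epithelial list 0.13 (IPs). fry, which tests a list on its own, gave let-7 0.056 and 0.10 in the resting and proliferating IP, 0.028 for the interaction and 0.0060 between IPs, and passed the epithelial list (0.0059 resting IP, 0.016 interaction, 0.0040 inputs), the miR-17 list (0.027, resting IP), the haematopoietic list (0.048, inputs) and the mirtron list (0.048 inputs, 0.035 IPs). Leaving out a library took the camera adjusted p of the miR-17 list over 0.024 to 0.10 in the resting IP and 0.0046 to 0.53 for the interaction, of the epithelial list over 0.027 to 0.16 for the interaction, and of the haematopoietic list over 0.037 to 0.45 in the proliferating IP, 0.029 to 0.49 for the interaction and 0.021 to 0.26 between inputs. Of 187 named log2 fold changes past the threshold, 186 kept their sign in all other settings. ENSMUSG00000076258.1 ranged from -1.97 (without resting IP replicate 2) to 8.90 for the interaction, and Mir27b in the proliferating IP, at 0.01, was -0.59 with library totals. Sign changes between values that both missed the threshold occurred for 56 of 303 named results. With the replicate number as a block the calls were 62, 60, 40, 100 and 109 for the 5 contrasts in the order resting IP, proliferating IP, interaction, input and within the IP, and 57, 55 and 32 with a block within cell state for the IP contrasts and the interaction. The main fit was planned without a block, because no label says that a number marks the same animal. Deviations of same-numbered libraries correlated across features at 0.026 and -0.0036 between IP and input and at -0.19 between states. Mir223 and Mir144 were nonetheless higher in replicate 2 in both the resting input and the resting IP, so pairing is not excluded. A crossed block gave 106 and 110 calls in input and IP. Interactions of 2-fold were recovered in 9.33% of simulated cases.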

Other observations

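The tests in this part were set before their results were seen, and the features named in this paragraph were chosen after their values were seen. The Mir183, Mir96 and Mir182 cluster on chromosome 6 (30165918 to 30169737 across the 3 genes, within Mirc35hg) was lower in resting than in proliferating cells. In the input Mir182 fell by 3.11, Mir183 by 3.59 and Mir96 by 3.54 on the log2 scale, and in the IP by 3.90, 3.92 and 2.91 (highest edgeR adjusted p = 3.1e-04). Mir132 and Mir212, neighbours on chromosome 11 known as CREB-induced miRNAs, were lower by 2.52 and 2.90 in the input. Mir296 and Mir298 on chromosome 2 were lower by 2.84 and 2.57 in the input and by 2.17 and 3.03 in the IP. The miR-7 genes Mir7-1, Mir7-2 and Mir7b, on chromosomes 13, 7 and 17, were lower by 1.06, 2.64 and 2.29 in the input and by 1.62, 2.96 and 2.58 in the IP, all past the threshold with edgeR, and reads of near-identical copies are not assigned with certainty. Mir223 was higher in replicate 2 than in replicate 1 in both the resting input (2.86% against 1.153%) and the resting IP (2.94% against 1.45%).

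A hypothesis was that neighbouring miRNA genes change together because they share transcription. Over 44 pairs of tested neighbours within 10 kb on the same strand, log2 fold changes between resting and proliferating input correlated with r = 0.44 (1-sided permutation p = 0.0009), and 81.8% of pairs had the same sign, which is consistent with shared transcription. Whether neighbours also share their IP enrichment was not settled: r was 0.0303 in resting cells (permutation p = 0.38) and 0.32 in proliferating cells (permutation p = 0.0087). Pairs in the same cluster are not independent, and the miR-17 paralogs make up part of them.

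Another hypothesis was that miRNA genes with high registry numbers, many of which were annotated late from few reads, are less often AGO2-bound. The 57 tested genes numbered above 1000 lay below the 155 others in median IP enrichment by a difference of -0.54 in resting cells and -0.53 in proliferating cells (2-sided permutation p = 0.029 and 0.016). Among features with a mean CPM of 10 to 200 the difference was -0.20 (42 against 64 genes, permutation p = 0.59) in resting and 0.0859 (permutation p = 0.87) in proliferating cells, so abundance may account for the first result.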
